A study of Mus musculus with 2 samples.

How the data were processed

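The data were 4 one-colour (Cy3) whole-mouse-genome oligonucleotide arrays of pooled hypothalamus RNA, 1 for each combination of diet (control or bezafibrate) and time (ZT10 or ZT22). Each pool held RNA of 4 mice, and 400 ng of total RNA was labelled. Each deposited sample held the bezafibrate array and the control array of the same time. Groups were taken from the labels. With 1 array per group, no spread between mice or pools could be estimated.

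Per the file headers, the authors scanned the arrays and extracted each spot with Feature Extraction 9.5.1.1. The deposited processed signal is an intensity from which background was subtracted and spatial trends were removed, with low values replaced by an error-based surrogate. It was written with 3 significant digits and was not normalized between arrays. The deposited files also held the error of that signal, the median intensity of each spot and of its local background, and other 0 or 1 marks per spot for well above background, saturation and outliers. Per the labels, the deposited value table of the series is a ratio of the bezafibrate array over the control array for present spots. Its scale and direction were checked against the array files. Each column was linear and correlated with the ratio of processed signals at r of 0.988 and 0.990 across spots, and it differed from that ratio by a constant log2 factor of -0.14 at ZT10 and 0.10 at ZT22, within 0.05 for 99.5% of the values. This table was used as an alternative only.

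The processed signal was taken to log2, and the 75th percentile over the features that were not controls was subtracted on each array. Control spots and outlier spots (73 to 142 per array) were left out, and spots of the same probe were averaged. Of 41174 probes, 22951 were named through the accession in the files, 5850 through a symbol and 3944 through an older symbol, using the RefSeq gene table of assembly GRCm38.p6 for names alone. Of the remainder, 2225 kept the name in the files and 6204 had no gene name. No gene coordinates were used. Each of the 21501 genes was represented by its probe with the highest mean signal over the 4 arrays, and 8876 genes had more than 1 probe. For some genes the value of another probe above background is given where it departed from the value printed.

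The comparisons were bezafibrate against control at ZT10 and at ZT22, and ZT22 against ZT10 in control and in bezafibrate mice. A gene entered a comparison when it was well above background on at least 1 of the 2 arrays. A gene dim on 1 of them counted through a bound, with the dim signal set to its limit, and such folds are given as at least the bound. The threshold was 2-fold for each comparison. It was 1.5-fold for genes alike at both times, which had to be above background on all 4 arrays. Expected numbers for both times are the products of the shares at each time. The error of a ratio was combined from the scanner software's signal errors.

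Of 36 gene lists, covering PPAR and lipid pathways, the clock, hypothalamic peptides and receptors, stress and immune responses, cell types, neighbouring tissues and housekeeping groups, members above background on all 4 arrays were used. The median log2 ratio of a list was ranked among 10000 random lists of the same size, whose genes were drawn within 100 ranks of mean expression. The ranking describes a pair of pools and gives no p-value, since genes of the same pool are not independent. The list of cold-inducible RNA-binding proteins had too few members for it.

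The lists, comparisons, thresholds and the rule for naming genes were fixed before the data were examined. The rule named the 10 highest and 10 lowest ratios at each time and the 5 highest and 5 lowest of each time comparison. It also named the 10 genes with the largest smaller ratio of like sign at both times in each direction, and the 5 largest bounds in each direction and time. List members at 1.5-fold at both times or 2-fold at 1 time were named, up to 6 per list, together with fixed genes (among them Npy, Agrp, Pomc, Cartpt, Hcrt, Pmch, Ppara, Pdk4, Angptl4, Cpt1a, Per1, Per2, Per3, Dbp, Nr1d1 and Arntl) and genes past an adjusted p of 0.05. Clones and numbered loci were not named, and parts of the rule were shortened. Single values of some genes that the rule names are not used here. Any other gene is said to have been chosen after its values were seen, which also holds for the count of genes that stood out on a single array.

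Effects of diet and time averaged over the other factor were fitted over the 4 arrays with limma 3.58.1 (lmFit and eBayes, Benjamini-Hochberg adjustment) for the 17543 genes above background on at least 1 array. This additive model left 1 residual degree of freedom, and the prior had 1.29. It assumes that diet acts alike at both times. A test of a difference between times was not possible, and leaving out 1 array left 0 degrees of freedom. Counting and list ranking were tested on simulated data for the 15918 genes above background on all 4 arrays. There, 100 of 100 raised and 100 of 100 lowered genes were counted and 0 others. The simulated shift lay well past the threshold and the noise lay below the scanner error. This checks the code and not the precision of the counts, least of all for dim genes. In simulated data for the limma fit with 200 changed genes among 17543, 0% were called at 1.5-fold and 2-fold and 51.5% at 4-fold, with 2 false calls.

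Alternatives changed 1 choice at a time, except for normexp, which also replaced the processed signal, and the deposited ratio table. That table differs in its constant factors and in being blank where the bezafibrate spot was not present. Its genes dim on the control array also counted by their full ratio and not through a bound. The alternatives were normexp background correction with an offset of 50, quantile normalization, cyclic loess, scaling to the median, the mean over the probes of a gene, no filter on dim probes, a filter for above background on all arrays compared, the other fold threshold, the deposited ratio table, an intensity trend in limma, and unadjusted p-values. A minimum mean signal of 100 was added after the data had been seen. Normexp was run on the median spot intensity, without the spatial detrending and the surrogates of the processed signal, because the mean spot intensity planned for it was not among the columns used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.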

Results

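Gene expression in the mouse hypothalamus was compared between animals given bezafibrate, a fibrate drug that activates the PPAR family of nuclear receptors, and control animals, to ask how a PPARα agonist acts on hypothalamic transcripts. A block of brain that held the hypothalamus was taken at ZT10 and at ZT22, zeitgeber times that count the hours from lights on. RNA of 4 mice of the same diet and time was pooled, and each of the 4 pools was hybridized to 1 one-colour array. By the barcodes in the file headers, the arrays shared 1 slide. The control pools were at positions 2 (ZT10) and 1 (ZT22), and the bezafibrate pools at positions 4 (ZT10) and 3 (ZT22). Diet therefore cannot be separated from the side of the slide. There were no replicates, so no p-value is given for any pair of arrays. The value after ± is the scanner software's error of a log2 ratio for the spots compared, and it covers neither the spread between mice nor that between pools. Per the labels, the mice were 8 weeks old at the start and had normal feed for 2 weeks, feed with 0.5% bezafibrate for 2 weeks and normal feed again for 5 weeks. The stage of this schedule at which the brains were taken was not settled by the labels.

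Of the 43379 features that were not controls, 74.6% were well above background on the control array at ZT10, 68.7% on the bezafibrate array at ZT10, 70.4% on the control array at ZT22 and 70.6% on the bezafibrate array at ZT22. The 75th percentile of the signal was 1010, 1050, 1010 and 893 intensity units on the same arrays, and no spot was saturated. Of 21441 genes with a measured probe, 15918 were well above background on all 4 arrays. Spots of the same probe on 1 array differed by a median SD of 0.08 in log2 signal on each array, and the median scanner error of a log2 ratio was 0.20. Different probes of the same gene differed in their log2 ratio by a median SD of 0.08 to 0.12, depending on the comparison. Of the 2-fold genes with another probe above background, that probe differed 1.5-fold in the same direction in 3 of 9 at ZT10, 5 of 22 at ZT22, 9 of 28 for time in control mice and 4 of 21 for time in bezafibrate mice. The number of arrays limits the precision of every comparison.

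At ZT10, the bezafibrate pool had lower levels of pituitary hormone transcripts than the control pool. It had higher levels of the transcripts of appetite-promoting peptides of the arcuate nucleus. Prolactin (Prl, NM_011164) was 22.3-fold lower (log2 ratio -4.48 ± 0.33) and growth hormone (Gh) was 13.1-fold lower (-3.72 ± 0.33). The Prl signal was 380 intensity units in the control pool and 17.7 in the bezafibrate pool. For Prl and Gh, pituitary tissue in the control pool cannot be told apart from an effect of diet with 1 pool per diet. Agouti-related peptide (Agrp, NM_007427), which stimulates feeding, was 1.97-fold higher (0.98 ± 0.20), and proopiomelanocortin (Pomc, NM_008895), the precursor of the satiety peptide α-MSH and of pituitary ACTH, was 2.21-fold lower (-1.15 ± 0.20).

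Among genes above background on both arrays, the highest ratio at ZT10 was that of Prim2, a DNA primase subunit, at 18.1-fold (4.18 ± 0.31). It was followed by Rnase10 (3.27 ± 0.35), the X-linked noncoding RNA Firre (2.96 ± 0.22), the homeobox gene Hlx (2.85 ± 0.32), Cfap74 (2.32 ± 0.26) and the R-spondin receptor Lgr6 (2.18 ± 0.22). In the control pool, Prim2, Rnase10 and Hlx had signals of 10.2, 10.1 and 11.6 units. Such signals lie near the background limit, so the size of these ratios is uncertain. Prim2 at 10.1 units in the bezafibrate pool at ZT22 was below that limit. Fam178b and the odorant receptors Olfr143, Olfr1261 and Olfr494 completed the 10 highest, with log2 ratios of 1.91 to 2.09. Besides Prl and Gh, the 10 lowest were the serine protease Prss43 (-4.29 ± 0.33), the membrane-bound transcription factor Creb3l1 (-2.85 ± 0.23), the plasmin inhibitor Serpinf2 (-2.64 ± 0.33), Aym1, Adamtsl5, Eps8l2, Hpvc2 and Wdr91 (-2.21 ± 0.23). In the bezafibrate pool, Gh and Prss43 were also near the limit, at 15.9 and 15.4 units. Among genes above background on 1 of the arrays, the retinal and pineal transcription factor Crx was at least 11.9-fold higher, Pnliprp2 at least 9.04-fold and Hoxd9 at least 7.97-fold. The water channel Aqp6 was at least 22.6-fold lower, the IGF-binding Igfals at least 17.5-fold and Syt15 at least 11.9-fold.

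Among the gene lists at ZT10, 10 of 11 measured pituitary markers were lower in the bezafibrate pool (median log2 ratio -0.31), among them Fshb (-0.80 ± 0.35) and Cga (-0.70 ± 0.20), the β subunit of follicle-stimulating hormone and the common α subunit of the glycoprotein hormones. Of 15 thalamus markers, 14 were lower (median -0.20), with Tnnt1 2.14-fold lower and Ramp3 at -0.81 ± 0.20. Of 22 interferon-induced genes, 18 were lower (median -0.18), as were 14 of 15 fibroblast and meninges markers (-0.19), 17 of 22 immediate early genes (-0.14) and 14 of 20 other hypothalamic neuropeptides and hormones (-0.13). Vasopressin (Avp) stood at -0.67 ± 0.20 and the guanylate-binding protein Gbp2 at -0.54 ± 0.20. The cortical genes Neurod2 (-1.55 ± 0.21; another probe -0.50) and Slc17a7, a vesicular glutamate transporter (-1.43 ± 0.26), were also lower, while their list of 16 cortex, hippocampus and amygdala markers had a median of -0.05. Markers of hypothalamic nuclei were higher in 17 of 26 (median 0.09). For these lists of brain regions and meninges, an unequal dissection cannot be told apart from an effect of diet with 1 pool per diet. Fshb, Cga, Ramp3, Avp and Gbp2 were chosen after their values were seen.

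In all, 119 genes were at least 2-fold higher and 142 at least 2-fold lower with bezafibrate at ZT10, of which 51 and 57 were above background on both arrays and the others passed through a bound. Of 16118 genes above background on both arrays, 97.56% differed by less than 1.5-fold. Among genes with a mean signal of at least 100 units the counts were 7 and 15, and after normexp correction of the median spot intensity they were 10 and 29. The balance turned to more genes higher in the deposited ratio table (115 higher, 72 lower) and under quantile normalization (146 and 117). The deposited table is blank where the bezafibrate spot was not present, and its ratios were counted without a bound. Of 35 lists, 14 had a median outside the central 95% of 10000 random lists matched on expression, a description of these pools and no test of the diet.

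**Figure D1:**
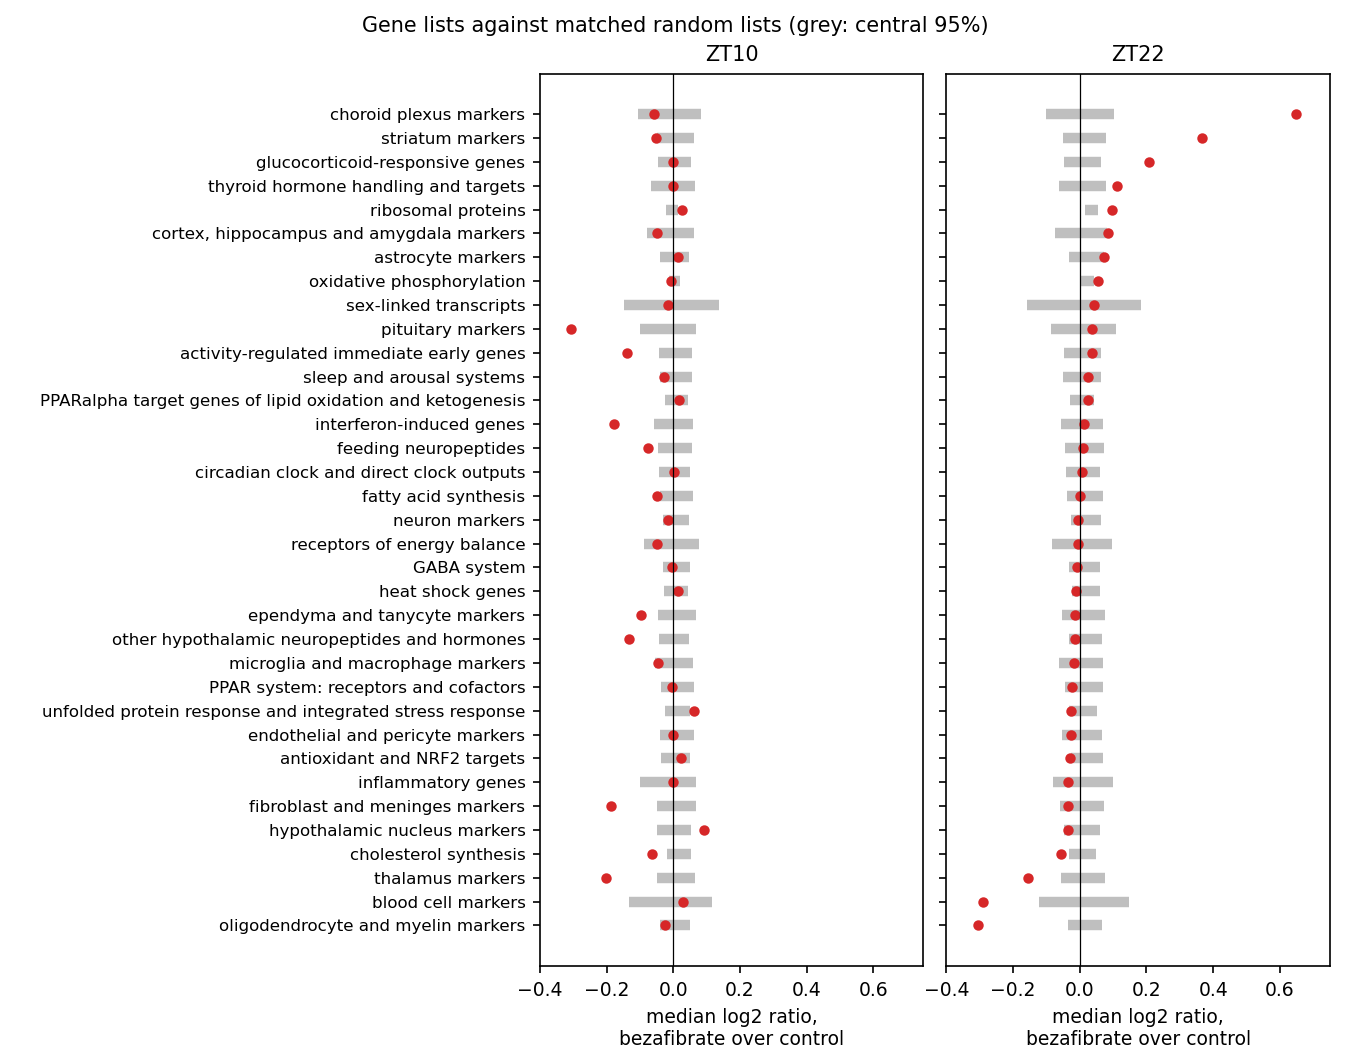
Median log2 ratio of bezafibrate over control (horizontal axis) for 35 gene lists at ZT10 and at ZT22, each panel 1 pair of arrays; red marks are the list medians and grey bars the central 95% of 10000 random lists matched on expression. The choroid plexus list lies at -0.06 at ZT10 and at 0.65 at ZT22, and the myelin list at -0.03 and -0.31.

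At ZT22, the bezafibrate pool had higher levels of choroid plexus and striatum transcripts and lower levels of myelin transcripts than the control pool. Transthyretin (Ttr, NM_013697), the thyroxine carrier made by the choroid plexus, was 13.6-fold higher (3.76 ± 0.21), with 110 intensity units in the control pool and 1320 in the bezafibrate pool. The potassium channel subunit Kcne2 was 5.88-fold higher (2.56 ± 0.22) and the water channel Aqp1 3.09-fold higher (1.63 ± 0.22). Of 13 choroid plexus markers, 11 were higher (median 0.65) and 7 by at least 1.5-fold, including Klotho (Kl, 0.89 ± 0.20) and Cldn2 (0.87 ± 0.29).

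Of 16 striatum markers, 15 were higher at ZT22 (median 0.37). Ppp1r1b, the phosphatase inhibitor DARPP-32, stood at 0.96 ± 0.20 and the dopamine receptor Drd1 at 0.89 ± 0.20. All 18 measured oligodendrocyte and myelin markers were lower (median -0.31), as in Mog (-0.51 ± 0.20) and Opalin (-0.49 ± 0.20). Of 19 glucocorticoid-responsive genes, 14 were higher (median 0.21), among them the metallothionein Mt2 (0.71 ± 0.20) and the kinase Sgk1 (0.67 ± 0.20). Thalamus markers were again lower (13 of 15, median -0.15). For the striatum, thalamus and myelin lists, unequal shares of tissue in the dissected blocks cannot be told apart from an effect of diet with 1 pool per diet. The pituitary list, lower at ZT10, had a median of 0.04 at ZT22, where Tshb, the β subunit of thyrotropin, was at 1.35 ± 0.21 by its brightest probe and at -0.09 by another. Prl was at least 5.47-fold lower and Gh at least 5.90-fold lower at ZT22 as well, both below the background limit in the bezafibrate pool. Kl, Cldn2, Ppp1r1b, Drd1, Mog, Opalin, Mt2 and Sgk1 were chosen after their values were seen.

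Among genes above background on both arrays, the highest ratios at ZT22 after Ttr were those of the protease Tmprss2 (3.29 ± 0.25), the chemokine receptor Ccr6 (2.87 ± 0.24), the transcription factor Gata5 (2.74 ± 0.28), Kcne2, Glipr1l1 (2.40 ± 0.31), Vmn1r81, Sh3rf2, hemojuvelin (Hjv, 1.81 ± 0.22) and Rhox5. The lowest were Firre (19.8-fold, -4.30 ± 0.24), Prss32 (16.3-fold, -4.03 ± 0.28), the pyruvate kinase Pklr (15.1-fold, -3.91 ± 0.25), the adrenergic receptor Adra2b (14.1-fold, -3.81 ± 0.27), Pde6h (-3.49 ± 0.25; another probe 0.25), Cd79a, Mbtps2, Fam163b, Umodl1 and Fscn3 (-2.70 ± 0.21). Some of these ratios rest on a signal near the background limit, as for Prss32 (14.3 units) and Cd79a (13.5 units) in the bezafibrate pool. By bound, Ankle1 was at least 21.6-fold higher, the growth factor Fgf2 at least 15.3-fold and Cldn34b3 at least 13.6-fold, while Bpifa1 was at least 58.1-fold lower, Rtp1 at least 39.0-fold and Olfr1099 at least 21.7-fold.

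The counts at ZT22 were 121 genes at least 2-fold higher and 293 at least 2-fold lower, 58 and 117 of them above background on both arrays, and 96.81% of 16215 genes differed by less than 1.5-fold. Of 96 genes at least 2-fold lower and above background on all 4 arrays, 64 were also at least 2-fold brighter on the control array at ZT22 than on the control array at ZT10, and for 49 of these the bezafibrate array at ZT10 was within 1.5-fold of the control array at ZT10 and of the bezafibrate array at ZT22. Other arrays also had genes apart from the rest: of the genes 2-fold brighter than in the other diet, 22 of 35 on the bezafibrate array at ZT10, 22 of 52 on the control array at ZT10 and 25 of 53 on the bezafibrate array at ZT22 were also 2-fold brighter than at the other time. These counts were chosen after the data were seen. Among genes with a mean signal of at least 100 units 18 were higher and 25 lower, and after normexp correction 28 were higher and 47 lower. The deposited ratio table turned the balance, with 177 higher and 137 lower. Of 35 lists, 13 had a median outside the central 95% of random lists.

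Few genes moved alike at both times. Agrp was 1.97-fold higher at ZT10 and 3.20-fold higher at ZT22 (1.68 ± 0.20), and neuropeptide Y (Npy, NM_023456), made by the same arcuate neurons, was 1.64-fold (0.72 ± 0.20) and 2.39-fold higher (1.26 ± 0.20). Among the other genes with the largest higher ratios in common were Ccr6 (2.14-fold and 7.30-fold), Lgr6 (2.18 and 1.03, with another probe at -0.76 at ZT22), Gata5 (0.93 and 2.74), Trim55 (0.65 and 0.71, with another probe at -0.45 and -0.01), the forkhead-regulated Depp1 (0.64 and 0.87), the glutathione peroxidase Gpx6 (0.64 and 0.76) and the amylase Amy2 (0.63 and 0.97). Lower at both times were Hpvc2 (-2.28 and -1.63), Prss43 (-4.29 and -1.49), Olfr1364 (-1.25 and -1.43), the secretoglobin Scgb3a1 (-1.18 and -1.27), the angiotensin-(1-7) receptor Mas1 (-0.96 and -1.07), Krt84, Hsd3b4, Cdkn3, Cthrc1 (-0.91 and -0.77) and Eps8l2. The Mas1 ratio at ZT22 was 0.15 when the probes of the gene were averaged.

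**Figure D2:**
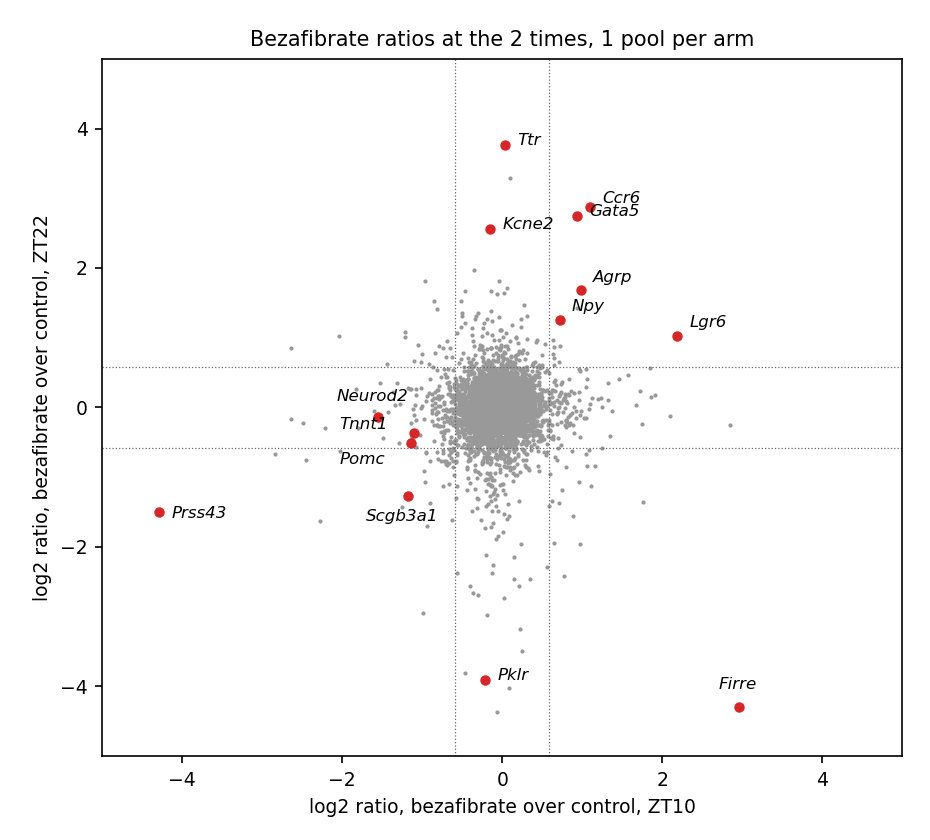
Log2 ratio of bezafibrate over control at ZT10 (horizontal axis) and at ZT22 (vertical axis) for the 15918 genes above background on all 4 arrays, each point 1 gene and dotted lines at 1.5-fold. Npy and Agrp lie in the quadrant higher at both times, Pomc is lower at both, and Ttr and Kcne2 lie near 0 at ZT10.

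At a threshold of 1.5-fold at both times, 13 of 15918 genes were higher and 37 lower, where independent ratios would give 1.63 and 3.49, and 20 genes moved in each of the opposite patterns, where 2.23 and 2.56 would be given. Across genes, which are not independent replicates, the log2 ratios at ZT10 and ZT22 had a Pearson r of 0.06 and a Spearman rho of 0.10. With normexp correction 3 genes were higher and 0 lower at both times, and with a mean signal of at least 100 units 5 and 8.

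Among the 14 measured feeding neuropeptides, the appetite-promoting Npy and Agrp and the appetite-suppressing Pomc had opposite signs at both times. Pomc was 2.21-fold lower at ZT10 and 1.43-fold lower at ZT22 (-0.52 ± 0.20). The anorexigenic transcript Cartpt stood at -0.36 ± 0.20 and -0.19 ± 0.20. The orexin precursor Hcrt (-0.09 and 0.32) and the melanin-concentrating hormone precursor Pmch (-0.01 and 0.22) of the lateral hypothalamus were within 1.5-fold at both times. The list's median was -0.08 at ZT10 and 0.01 at ZT22. Npy, Agrp and Pomc were measured by 1 probe each. Pituitary markers, of which Pomc is one, were lower at ZT10 in the same pools.

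**Figure D3:**
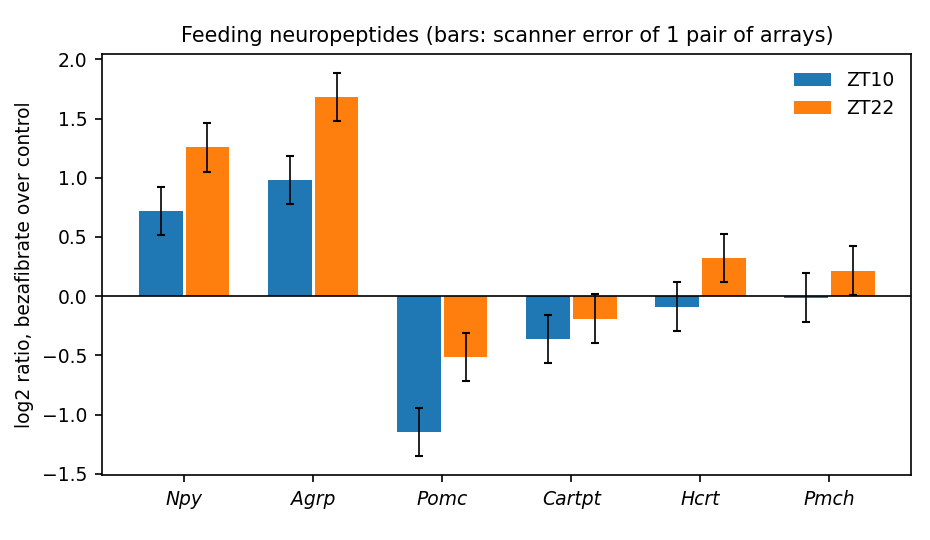
Log2 ratio of bezafibrate over control for 6 feeding neuropeptides at ZT10 and ZT22, bars from 0, each from 1 pair of arrays, with error bars for the scanner error of the spots. Npy and Agrp are above 0 and Pomc below 0 at both times, from 1.68 for Agrp at ZT22 to -1.15 for Pomc at ZT10.

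The PPARα target genes of lipid oxidation and ketogenesis showed no common shift. Of 40 measured members, 22 were higher at ZT10 (median log2 ratio 0.02) and 24 at ZT22 (median 0.02, mean -0.02), and none differed by 1.5-fold at either time. Pdk4, the kinase that restrains pyruvate oxidation, was at 0.08 ± 0.20 and 0.22 ± 0.20, Cpt1a, which carries fatty acids into mitochondria, at 0.01 and 0.01, and the lipase inhibitor Angptl4 at -0.02 and -0.45. The receptor Ppara itself was at 0.01 ± 0.21 and -0.03 ± 0.21, and the 15 receptors and cofactors of the PPAR system had medians of -0.01 (mean 0.00) and -0.02 (mean 0.02). The PPARα list lay at the 60.98th and 83.06th percentiles of random lists. Its median was -0.07 and -0.05 in the deposited ratio table, whose columns each carry a constant factor.

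Cholesterol synthesis genes were slightly lower with bezafibrate at both times, in 20 of 24 members at ZT10 (median -0.06) and 19 of 24 at ZT22 (median -0.06). Dhcr7, the last enzyme of cholesterol synthesis, stood at -0.31 ± 0.20 and -0.19 ± 0.20, the sterol sensor partner Insig1 at -0.16 and -0.36, and Cyp51 at -0.22 and -0.17. Fatty acid synthesis genes had medians of -0.05 and 0.00. Both medians of the cholesterol list were outside the central 95% of random lists, -0.02 to 0.05 at ZT10 and -0.03 to 0.05 at ZT22. So were the medians of many lists, 14 of 35 in all at ZT10 and 13 of 35 at ZT22. These 3 genes were chosen after their values were seen, and each single ratio was within 2 scanner errors of 0. In the same pools all 18 myelin markers were lower at ZT22 (median -0.31, against -0.03 at ZT10), and a link between the 2 lists was not tested.

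Most clock transcripts, 20 of 24, differed between ZT22 and ZT10 in the same direction in control and in bezafibrate mice. Among all genes, 67.8% had the same sign in both diets. Dbp (NM_016974), a direct output of the clock, was 2.40-fold lower at ZT22 in control mice (-1.26 ± 0.20) and 1.44-fold lower in bezafibrate mice (-0.53 ± 0.20). The period genes Per1 (-0.45 and -0.31), Per2 (-0.45 and -0.39) and Per3 (-0.64 and -0.58) and the repressor Ciart (-0.99 and -0.51, chosen after its values were seen) were also lower, and Arntl, which encodes the activator BMAL1, was higher (0.49 and 0.34). Nr1d1, which encodes the repressor REV-ERBα, was at -0.90 ± 0.20 and -0.27 ± 0.20, although its other probes gave 0.60 and -0.10 in control mice and -0.31 and 0.28 in bezafibrate mice. Another probe of Per2 gave -0.50 in control and -0.06 in bezafibrate mice. Of 24 clock genes, 16 were lower at ZT22 in control mice (median -0.16) and 14 in bezafibrate mice (median -0.15). The bezafibrate ratio itself had a median of 0.00 at ZT10 (mean -0.02) and 0.01 at ZT22 (mean 0.10) over this list.

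**Figure D4:**
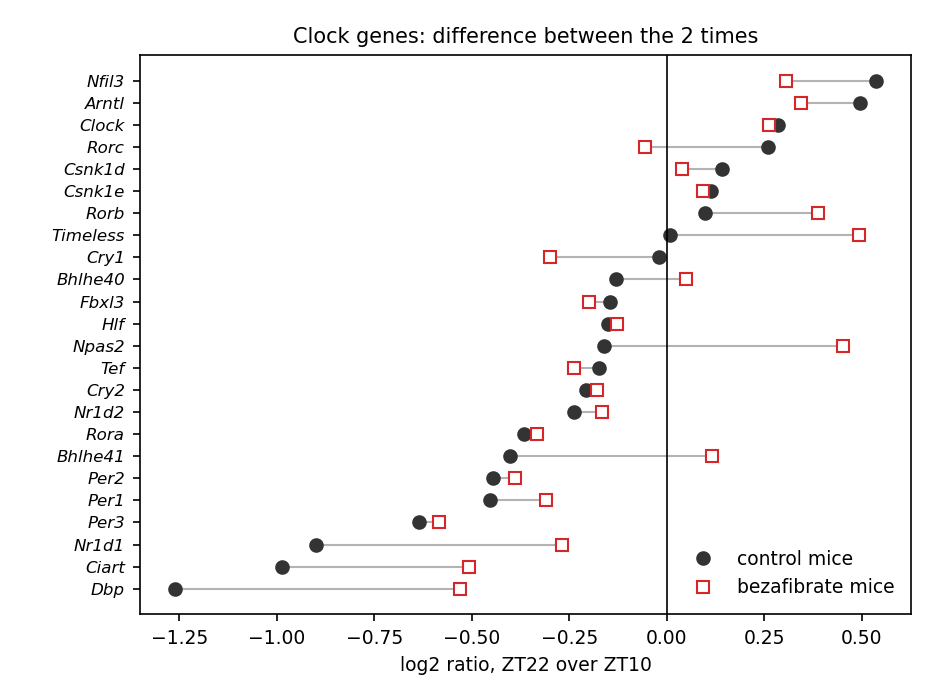
Log2 ratio of ZT22 over ZT10 for 24 clock genes in control mice (filled circles) and bezafibrate mice (open squares), each value from 1 pair of arrays. Dbp lies at -1.26 in control and -0.53 in bezafibrate mice, and Arntl at 0.49 and 0.34.

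Heat shock genes were higher at ZT22 in both diets, in 19 of 20 members each (medians 0.22 and 0.24), with the chaperone Hspa1a at 0.68 ± 0.20 and 0.54 ± 0.20. Glucocorticoid-responsive genes were lower in 14 of 19 in either diet (medians -0.37 and -0.11), with Sgk1 at -1.15 in control and -0.58 in bezafibrate mice and the lipid droplet protein Plin4 at -0.97 and -0.65. Fibroblast and meninges markers were higher at ZT22 (13 of 15, median 0.36, and 14 of 15, median 0.67), as in the GABA transporter Slc6a13 (0.78 and 0.86). Choroid plexus markers were higher in 11 of 13 in control mice (median 0.18) and in all 13 in bezafibrate mice (median 0.89), where Ttr was 24.8-fold higher (4.63 ± 0.23). Other lists took opposite signs in the diets: striatum markers were lower in 14 of 16 in control mice (median -0.19) and higher in 15 of 16 in bezafibrate mice (0.30), pituitary markers had medians of -0.20 and 0.41, and myelin markers of 0.12 and -0.18. Unequal dissection of the pools cannot be told apart from effects of time or diet in these lists. Of the cold-inducible RNA-binding proteins, Cirbp was at -0.50 and -0.42 and Srsf5 at 0.11 and 0.20. Hspa1a, Sgk1, Plin4, Slc6a13, Cirbp and Srsf5 were chosen after their values were seen.

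Among genes above background on both arrays, the receptor-transporting protein Rtp1 was 33.3-fold higher at ZT22 in control mice (5.06 ± 0.27), followed by Cyp2c23 (17.4-fold, 4.12 ± 0.33), Firre (4.12 ± 0.22), Pde6h (3.97 ± 0.25; another probe -0.52) and Pklr (3.89 ± 0.23). Rtp1 and Cyp2c23 were near the background limit in the control pool at ZT10, at 14.3 and 9.65 units, so the size of their ratios is uncertain. The chitinase-like Chil3 was 14.3-fold lower (-3.84 ± 0.21), followed by Prss43 (-3.08), Olfr385 (-2.72), Prl (6.42-fold, -2.68 ± 0.22) and Creb3l1 (-2.65). In bezafibrate mice, with the same limit, Ttr was followed by Tmprss2 (13.2-fold), Kcne2 (10.7-fold), Olfr791 and Rhox5, and the lowest were Chil3 (10.2-fold, -3.34 ± 0.21), Firre (-3.15), Rnase10 (-2.66), Hlx (-2.64) and Olfr868 (-2.03). At least 2-fold higher at ZT22 were 302 genes in control and 142 in bezafibrate mice, and 192 and 142 were at least 2-fold lower. After normexp correction the counts were 57 and 32 higher and 27 and 9 lower, and with a mean signal of at least 100 units 28 and 23 higher and 27 and 8 lower. Of 35 lists, 18 in control and 17 in bezafibrate mice had a median outside the central 95% of random lists. Across 15918 genes the control and bezafibrate time ratios had r of 0.285 and rho of 0.395, with 46 genes higher and 82 lower by 1.5-fold in both diets, against 5.75 and 4.37 for independent ratios. Each of these comparisons shares its arrays with the diet comparisons. Rtp1, Pde6h and Pklr, for instance, were bright on the control array at ZT22 alone, and so were high for time and low for diet through the same array.

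Averaged over both times in limma, with diet and time as terms over all 4 arrays, the log2 effect of bezafibrate was 1.33 for Agrp, 0.99 for Npy and -0.83 for Pomc, each at an adjusted p of 0.87. None of 17543 genes passed an adjusted p of 0.05 for diet in limma, with 953 at an unadjusted p under 0.05 (314 higher, 639 lower). The smallest adjusted p for diet was 0.725, of Prl, within a range of smallest values of 0.00382 to 0.999 over the alternatives. For time, limma also gave 0 genes, with 1895 at an unadjusted p under 0.05 (1088 higher at ZT22, 807 lower) and a smallest adjusted p of 0.439, within a range of 0.0251 to 0.608. With a mean signal of at least 100 units, a filter chosen after the data were seen, Prl passed for diet and for time, although it was below background on the bezafibrate array at ZT22.

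Adjusted over the list alone, Prl passed for diet in limma among 14 pituitary markers (adjusted p = 0.000578) and the thalamic transcription factor Shox2 among 16 thalamus markers (adjusted p = 0.0195), against 0 of these over all genes. Both p-values rest on signals below the background limit, of 2.41 units for Prl on the bezafibrate array at ZT22 and of 12.1 and 7.79 units for Shox2 on the bezafibrate arrays at ZT10 and ZT22. Adjusted over the list alone, time was passed by Cirbp (3 tested), by Ccl4, Cxcl12 and S100a9 (15 inflammatory genes), by Myh11 (20 endothelial and pericyte markers), by Col1a1, Slc6a13, Aldh1a2 and Ogn (15 fibroblast and meninges markers) and by Prl, with the same dim value, again against 0 over all genes. No member of the PPARα target, feeding or clock lists passed for either term over the list alone in limma, with 0, 4 and 0 members at an unadjusted p under 0.05 for diet and 2, 0 and 10 for time. The fit had 1 residual degree of freedom, and on simulated data it called 0% of genes changed 2-fold and 51.5% of genes changed 4-fold.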

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

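The bezafibrate ratio had opposite signs at ZT10 and ZT22, with a size of at least 1.5-fold at each time, in 9 named genes. None of these differences was tested, since each time has 1 pair of arrays, and the size of 1.5-fold was set after the data had been seen. Each difference is the log2 ratio at ZT22 minus that at ZT10, with genes below background taken at their bound.

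Prim2, a DNA primase subunit, was at 4.18 at ZT10 and -0.98 by bound at ZT22, a difference of -5.16. The noncoding RNA Firre was at 2.96 and -4.30, a difference of -7.27. The odorant receptor Olfr1261 was at 1.95 and -1.62 by bound, a difference of -3.57. The plasmin inhibitor Serpinf2 was at -2.64 and 0.85, a difference of 3.48. The homeobox gene Rhox5 was at -0.97 and 1.81, a difference of 2.78. Crx, a transcription factor of retina and pineal gland, was at 3.57 and -1.23, both by bound, a difference of -4.80. Igfals was at -4.13 and 0.60, both by bound, a difference of 4.73. Ankle1 was at -2.24 and 4.43, both by bound, a difference of 6.67. The peroxisomal aminotransferase Agxt was at -1.83 and 3.69, both by bound, a difference of 5.52. The highest signal of these genes on any array was 552 units, for Firre on the control array at ZT22.

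Among 2369 probes without a gene name that were above background on all 4 arrays, which no other comparison uses, 2 were at least 1.5-fold higher with bezafibrate at both times, where independent ratios would give 1.73. In the other direction 8 were at least 1.5-fold lower, where 2.01 would be given.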

How the results depend on the processing

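The minimum mean signal of 100 units was chosen after the data had been seen, and the other alternatives before. Under quantile normalization, cyclic loess and median scaling, every count of genes for a diet or time comparison stayed within 1.5 times the reported count, except the count higher at both times under quantile normalization, which was 21. The correlation between times was 0.0453 there. Over all alternatives, 1317 single-gene values kept to within their error, 166 moved beyond it (110 of them under normexp) and 1 reversed, and of the list medians 674 kept, 216 moved and 6 reversed. Of the 1317, 176 came from the filter for above background on all arrays compared, which cannot change the value of a gene that passes. Dropping the filter on dim probes likewise can change a single-gene value only where the gene was dim on 1 array. Signal over background limits the counts, since most genes past 2-fold had mean signals under 100 units. The cause was not tested for any change below. The exceptions are a stricter or looser filter or threshold, which sets which genes can be counted, and the normexp offset, which draws the ratios of dim genes toward 0.

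Normexp background correction added an offset of 50 to each intensity, so that fewer dim genes could pass 2-fold, and put the median spot intensity in place of the processed signal. With it, 10 genes were higher and 29 lower at ZT10, 28 and 47 at ZT22, 3 and 0 at both times, 57 higher and 27 lower at ZT22 in control mice, and 32 and 9 in bezafibrate mice. The correlation between times was 0.016, and the NRF2 target list reversed to 0.0021 for time in bezafibrate mice. The share of counted genes that was higher became 25.6% (from 45.6%) at ZT10 and 78.0% (from 50%) for time in bezafibrate mice.

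With the mean over all probes of a gene, the correlation between times was 0.0288 and Mas1 at ZT22 reversed to 0.149.

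Requiring genes above background on all arrays compared left 51 and 57 at ZT10, 58 and 117 at ZT22, 151 and 108 for time in control mice and 64 and 55 in bezafibrate mice. Without a filter on dim probes there were 328 higher and 516 lower at ZT10, 421 and 629 at ZT22, 193 and 287 at both times, 569 and 533 for time in control mice and 459 and 383 in bezafibrate mice. The correlation was then 0.0042, the sleep list reversed to 0.0354 for time in control mice, the NRF2 list to 0.0183 for time in bezafibrate mice, and the share higher at ZT22 was 40.1% (from 29.2%).

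A threshold of 1.5-fold gave 245 and 408 at ZT10, 338 and 591 at ZT22, 598 and 523 for time in control mice and 504 and 405 in bezafibrate mice, and one of 2-fold at both times gave 2 and 4. Unadjusted p-values under 0.05 in limma numbered 953 for diet and 1895 for time, and an intensity trend left 0 for both.

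With a mean signal of at least 100 units the counts were 7 and 15 at ZT10, 18 and 25 at ZT22, 5 and 8 at both times, 28 and 27 for time in control mice and 23 and 8 in bezafibrate mice, with a correlation of 0.0439. The shares higher were 31.8% (from 45.6%), 41.9% (from 29.2%), 50.9% (from 61.1%) and 74.2% (from 50%). In limma, 1 gene passed for diet and 1 for time, with fewer genes tested.

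In the deposited ratio table, 72 genes were lower at ZT10 (share higher 61.5%), 137 lower at ZT22 (56.4%) and 7 higher at both times. The PPARα target list was at -0.0733 and -0.0492. The unfolded protein response list reversed to -0.0291 and the ribosomal list to -0.0604 at ZT10, and the oxidative phosphorylation list to -0.0189 at ZT22, where the constant factor of each column put the median of all genes at -0.08 at ZT10 and -0.07 at ZT22.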

Other observations

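Of the tests on 3 patterns given here, those on choroid plexus tissue, on an effect present at both times, on the share of the arcuate nucleus (both tests), on pituitary tissue and on the phase or amplitude of the clock were chosen after the result was seen.

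Ribosomal protein genes were higher with bezafibrate in 65 of 95 at ZT10 (median 0.03, or -0.06 in the deposited ratio table) and in 87 of 95 at ZT22 (0.10), and oxidative phosphorylation genes had medians of -0.01 and 0.06 (-0.02 at ZT22 in the deposited table). Genes that handle or answer to thyroid hormone, a list that shares Ttr with the choroid plexus list, were at 0.00 (mean 0.06) and 0.11, with the thyroid hormone-binding Crym at 0.32 and 0.97. Ependyma and tanycyte markers were lower in 10 of 13 at ZT10 (-0.10) and at -0.01 at ZT22 (mean 0.14), where the tanycyte transcription factor Rax was at 0.87. The 4 measured blood cell markers were all lower at ZT22 (-0.29, and 0.03 at ZT10 with a mean of -0.05). Astrocyte markers were at 0.01 (mean -0.03) and 0.07, microglia and macrophage markers at -0.05 and -0.02, neuron markers at -0.02 and 0.00 (mean 0.02), and endothelial and pericyte markers at 0.00 and -0.03. Crym and Rax were chosen after their values were seen.

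Genes of the unfolded protein response were higher in 16 of 23 at ZT10 (median 0.06, or -0.03 in the deposited table) and at -0.03 at ZT22, and antioxidant NRF2 targets were at 0.02 and -0.03. Inflammatory genes were at 0.00 (mean 0.05) and -0.03, sleep and arousal genes at -0.03 (mean 0.01) and 0.03, GABA system genes at 0.00 and -0.01 (mean 0.03), receptors of energy balance at -0.05 and 0.00, and 4 sex-linked transcripts at -0.02 and 0.04. In the receptor list, the ghrelin receptor Ghsr was 2.38-fold lower at ZT22 by its brightest probe and at 0.35 by another. Interferon-induced genes were also lower at ZT22 than at ZT10 in control mice (17 of 22, median -0.20) and at 0.04 in bezafibrate mice (mean -0.01). The prostaglandin D synthase Ptgds, of the sleep list, was at 0.61 and 0.62 for ZT22 over ZT10 in control and bezafibrate mice, and was chosen after its values were seen.

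Choroid plexus markers were higher in the bezafibrate pool at ZT22. The tables argue against scaling between arrays, since the lowest list median under the other normalizations was 0.372, with normexp, above the upper end of 0.119 of the central 95% of random lists. An effect of bezafibrate present at both times would need a higher median at ZT10, where it was -0.059. Choroid plexus tissue in the dissected block, with Ttr at 1320 units in that pool, may account for the median of 0.65, but that median is the pattern itself, and the 2 list members left out of it, both higher, are too few to decide. An effect of bezafibrate at ZT22 alone was not tested.

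Npy and Agrp were higher and Pomc lower with bezafibrate at both times, and scaling does not account for the signs, since under the other normalizations the ratio nearest to 0 was -0.516, of Pomc at ZT22. A different share of the arcuate nucleus as the cause for all 3 genes would move Agrp and Pomc alike, whereas they had opposite signs, which is part of the pattern itself. Their log2 ratios differed by 2.125 at ZT10 and 2.193 at ZT22. The SD for a pair of genes was 0.211 and 0.254, taken over genes with a mean signal of at least 100 units, a filter added after the data had been seen. Of random pairs of such genes, 0.061% differed as much at ZT10 and 0.102% at ZT22, while Agrp and Pomc were picked after their values were seen. Among Npy, Agrp and Pomc, pituitary tissue in the control pools could account for Pomc alone. It cannot be told apart there, because Gh and Prl were lower than Pomc at both times while the median of the other 10 pituitary markers was -0.264 at ZT10 and 0.099 at ZT22. Against it stands that from ZT10 to ZT22 in the control pools Prl was 6.42-fold and Gh 3.15-fold lower while Pomc was at 0.02 ± 0.20, although each transcript may also vary with time by itself. A larger arcuate share as the cause for Npy and Agrp alone would also raise the arcuate transcripts Ghrh, Kiss1, Tac2 and Cartpt, each also made elsewhere. They had a median of -0.252 at ZT10 (-0.43 to -0.12) and of -0.166 at ZT22 (-0.55 to 0.45). Their values argue against such a share at ZT10, where all were below 0. At ZT22 they do not decide it, since Ghrh was at 0.447. An effect of bezafibrate and unequal sampling within the nucleus stay open.

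The time-of-day differences of the clock genes had a slope of 0.501 of the bezafibrate on the control log2 ratios, and 15 of 24 genes had a smaller difference of the same sign in bezafibrate mice, while others, such as Timeless (0.01 and 0.49, chosen after its values were seen), had a larger one. Regression to the mean of differences first seen in the control pools may give such a slope, but the comparison made for it cannot decide. Lists matched on the control difference and on signal had a median slope of 0.344 (95% from -0.161 to 0.764), and the clock list lay at their 76.2th percentile. Their genes were picked from all genes by the control difference, so they regress through that choice, whereas the clock list was fixed beforehand. Dbp was poorly matched, with -0.28 in its matched genes. The highest slope under the other normalizations was 0.528, so scaling does not account for it. A shift of the clock's phase or amplitude with bezafibrate, for which the slope of 0.501 is the measure, cannot be told apart from that regression with 1 pool at each of 2 times.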
